A study of Homo sapiens with 2 samples.

How the data were processed

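RNA from A549 cells, an established human lung adenocarcinoma line with epithelial morphology, was measured on Affymetrix expression arrays after 4 h in static culture or 4 h in stretch culture. The series holds 2 arrays, 1 per culture condition. Each array's group was taken from the sample's source name. The title of the stretched sample transposes digits of the line's name, while its source name gives A549. Per the labels' protocols, cells were pelleted and washed, total RNA was extracted on silica columns with the RNeasy kit, and biotin-labelled cRNA was hybridised. The amplitude, frequency and device of the stretch were not given in the sources used here, nor was the number of cultures behind each RNA.

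The deposited table holds log2 values for 53617 probe sets on each array. Per the submitters' processing notes, these are RMA values (robust multi-array average, which corrects background, quantile-normalizes and summarises the probes of a probe set on the log2 scale). The software, its version and the chip definition were not given in the sources used here. The log2 scale was read from the values, which lie between 0.60 and 12.7. The 2 columns were not on a shared distribution as deposited: their sorted values differed by up to 0.45, and the medians were 2.57 for the static and 2.47 for the stretched array. How the arrays were normalized to each other therefore stays unknown. RMA values carry no detection calls, and low signals are compressed, so a fold from a dim signal can understate the change in RNA. For genes picked as extremes, noise can also overstate the change.

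Probe sets were named through the platform's annotation table, with symbols checked by gene identifier against the NCBI RefSeq gene table of GRCh38.p14. The table gave 1 symbol to each of 16098 probe sets and several to 0. The other 37519 probe sets are unnamed here. The named probe sets covered 14884 genes, and 779 of these had more than 1 probe set. The probe set with the highest mean of the 2 arrays stood for the gene. Genes entered counts when the higher of their 2 values reached 2.52, the median of all values, which left 10981 genes. No genome build of the array design was named, so no coordinates are given. Control probe sets were not identifiable by name, so the planned comparison of spiked-in controls and of 3' against 5' probe sets was not made. The planned removal of cross-hybridising probe set types was not run either, because the identifiers carry no type suffix.

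With 1 array per condition no test across samples exists, and no p-value is given. The log2 difference is stretch minus static throughout. Genes were counted at a difference of 1 or more (2-fold), and list members at 0.585 or more (1.5-fold). For each of 30 gene lists, the median difference of the measured members was placed among the medians of 10000 random lists of the same size, drawn from named genes in 20 bins of mean level. Such a percentile describes these 2 arrays and not the reproducibility of the conditions. A level-adjusted difference, the deposited difference minus a loess curve (span 0.3) of difference on mean level over all probe sets, was used as an alternative and is given where it alters whether a list lay inside the middle 95%. The scale of array noise at low signal was taken from 26 measured genes of unrelated tissues. Their signals also set an upper bound for background at 4.55, their 95th percentile. Arrays were also simulated with 1 noise SD for all levels and without the level trend. There, 99.5% of 200 genes changed by a log2 size of 2 were recovered among 14884 genes. Of unchanged genes 1.47% passed 2-fold, and 2.00% of unshifted lists lay outside the middle 95%. In the data, the SD of differences was 0.24 in the lowest of 10 level bins, largest at 0.89 in bin 8, and 0.83 in the highest bin. The simulated shares therefore do not give the share of genes that noise would put past 2-fold in the data.

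The groups, lists, counts, thresholds and alternatives were fixed before the data were examined. The named genes are TNF and its receptors (both receptors are unnamed here), the 14 highest and 14 lowest eligible genes, and up to 4 members per list with the largest differences. A gene was eligible when it passed the level filter and most of its probe sets past that filter had the sign of the chosen one. Symbols of uncharacterised loci, long intergenic and antisense RNAs, microRNA and small nucleolar RNA genes, pseudogenes whose symbol ends in P and 1 digit, and Y-linked genes were left out. Where other genes are given, they were chosen after their values were seen, and this is said beside them. Alternatives were other level filters, the mean of all probe sets, 4 other normalizations, other fold thresholds, means in place of medians and unmatched random lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.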

Results

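Gene expression was compared between A549 lung adenocarcinoma cells held under static conditions and cells subjected to mechanical stretch for 4 h. The title of the series names invasion and tumour necrosis factor alpha, so the TNF pathway and genes of matrix invasion are reported alongside genes known to respond to mechanical load. Each condition was represented by 1 array with 53617 probe sets, and no value below has a replicate. The number of arrays limits the precision. Signals ranged from 0.61 to 12.7 on the static array and from 0.60 to 12.6 on the stretched array, and correlated with r = 0.946 across probe sets, which are not independent replicates. Among 26 genes of unrelated tissues, used as a guide to background, the difference between arrays had a robust SD of 0.48 on the log2 scale. Of these genes, 0 differed by 2-fold. Their median level was 2.15 and 12 of them passed the level filter, so they give no scale of noise for brighter genes. Over 10 level bins, the SD of probe set differences was largest in bin 8, at 0.89. That bin holds mean signals from 3.77 to 4.76, around the background bound. In the brightest bin the SD was 0.83. Real changes also enter these values.

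Many more of the named genes were higher than lower on the stretched array. Of 10981 genes past the level filter, 1349 were at least 2-fold higher and 275 at least 2-fold lower under stretch. Genes higher thus made up 83.1% of both. Of the 1349, 743 had a static value within the background range, and 215 of the 275 had a stretched value within it. The median difference of the 10981 genes was 0.20, with an interquartile range from -0.17 to 0.65. Over all probe sets, named or not, it was -0.04. The shift depended on level. Over 10 equal bins of mean signal, probe sets in bin 4 had a median difference of -0.15 and those in bin 9 one of 0.41. The split moved with the scaling and the filter. Genes higher made up 89.1% (1693 higher against 207 lower) after centring on the medians, and 88.4% and 89.2% with the level filter at the upper quartile and the background bound. They made up 68.2% after a loess on level, 61.5% after quantile normalization, and 28.4% (475 higher against 1198 lower) when the arrays were centred on reference genes. Centring on reference genes lowers every difference by 0.45, so a gene or list median between 0 and 0.45 has the opposite sign under that scaling. Gene lists are therefore given relative to random genes of the same level. At the 1.5-fold used for list members, 3042 of the 10981 genes were higher and 977 lower. Counts of list members higher and lower carry this lean and are to be read against it. Of 28 measured lists, 5 lay above the middle 95% of random lists and 0 below, where random draws of genes would put 1.4 outside. Members of a list can vary together and some lists share members. The 1.4 is therefore not the number to be found without an effect of stretch. Against random lists not matched on level, those of TNF and NF-κB response (99.3), TNF signalling (99.7), immediate early (99.4), ER stress (99.7) and NRF2 target genes (98.5) also lay above. For genes with further probe sets of different value, all of these had the sign of the chosen one in 47 of 68 genes past 2-fold, against 124 of 234 genes under 1.5-fold.

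**Figure D1:**
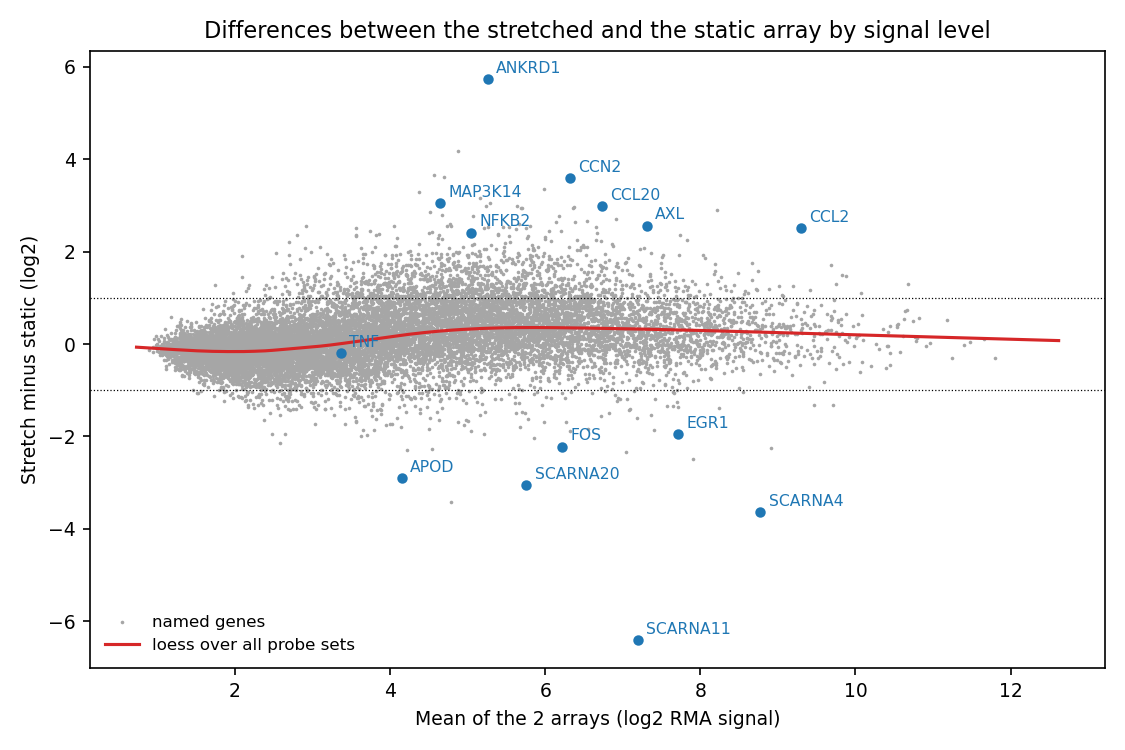
Difference between the stretched and the static array (log2) against the mean log2 RMA signal of the 2 arrays, with 1 grey point per named gene, the loess curve over all probe sets in red and dotted lines at 2-fold. ANKRD1 lies at 5.74 and SCARNA11 at -6.40, while TNF lies near the curve at a low level.

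Among the eligible genes, which leave out microRNA genes and other symbol classes, the highest difference was that of ANKRD1, a stretch-inducible ankyrin repeat protein and YAP target, which went from 2.39 on the static to 8.13 on the stretched array, a log2 difference of 5.74 (53.4-fold). MAMLD1 (3.65), TRIML2 (3.62) and CCN2 (3.59), the matricellular connective tissue growth factor, came next. With both of its probe sets averaged, CCN2 stood at 2.28. They were followed by PVR (3.36), the poliovirus receptor and nectin-like adhesion molecule, and by MAP3K14 (3.05), the NF-κB-inducing kinase. NAV3 (3.05), CCL20 (2.99), ATG16L1 (2.99), STK17A (2.98), STC2 (2.97), RRN3 (2.95) and ELOF1 (2.95) completed the group together with the processed pseudogene HNRNPA1P33 (2.94), a gene copy whose signal is uncertain because it resembles its parent gene. CCL20 encodes a chemokine, ATG16L1 an autophagy factor and RRN3 an initiation factor of RNA polymerase I. For 11 of these 14 genes, all but CCL20, STC2 and HNRNPA1P33, the static value lay within the range of the unrelated-tissue genes (up to 4.55), so that their differences are compressed and their order is not firm.

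At the other end, 6 of the 14 lowest eligible genes were small Cajal body RNAs, which guide the modification of spliceosomal RNAs. SCARNA11 went from 10.39 to 3.99 (a difference of -6.40), SCARNA4 from 10.59 to 6.96 (-3.63), SCARNA3 from 6.50 to 3.08 (-3.42) and SCARNA20 from 7.28 to 4.23 (-3.05). SCARNA6 (-2.48) and SCARNA8 (-2.33) were also among them. Of all 23 small Cajal body RNAs past the level filter, 12 were at least 2-fold lower and 1, SCARNA9L, was at least 2-fold higher, within the background range on both arrays. Their median difference was -1.03. The protein-coding genes at this end were APOD (-2.90), encoding the lipocalin apolipoprotein D, RASSF9 (-2.27), FOS (-2.22), CCL11 (-2.14), BTBD8 (-1.97), EGR1 (-1.95), TREML4 (-1.94) and PIERCE2 (-1.89). CCL11 and TREML4 lay within the background range on both arrays. The stretched values of SCARNA11, SCARNA3, SCARNA20, APOD, RASSF9 and BTBD8 lay within it too. Compression may have shrunk their differences, and picking the lowest genes may have favoured differences enlarged by noise, so their order is not firm.

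The TNF transcript itself was not higher under stretch. Its signal was 3.46 on the static and 3.27 on the stretched array, a difference of -0.19, within the background range on both. Of its 8 annotated probe sets, 7 gave these same values, and the remaining one read 2.58 and 2.55. The 16 measured members of the TNF signalling list (26 fixed) had a median difference of 0.61, against 0.365 for random lists, at the 91.1st percentile. Of these members, 8 were at least 1.5-fold higher and 0 lower. TAB1 (1.05), CFLAR (0.98), RELA (0.87) and BIRC2 (0.84) had the largest differences among them, TAB1 from a static value within the background range. With all probe sets of a gene averaged, TAB1 stood at 0.26 and this list's percentile was 55.0.

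Among genes induced by TNF and NF-κB, several had large differences. CCL20 went from 5.24 to 8.23 (2.99), CCL2, the monocyte chemoattractant, from 8.04 to 10.55 (2.51), NFKB2, the p100 precursor, from 3.84 to 6.25 (2.41) and the adhesion molecule ICAM1 from 2.92 to 4.64 (1.72), the last 2 from static values within the background range. Of the 21 measured members (32 fixed), 10 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 9 between. Their median difference was 0.48, at the 94.4th percentile of random lists and inside the middle 95%, but this depended on the level filter and the statistic. Over the 19 members past the level filter the median was 0.65 (98.2nd percentile), and with the filter at the upper quartile and the background bound it was 1.05 and 1.16 (99.98th and 100th). The mean of all members lay at the 99.9th percentile. Chosen after their values were seen, CXCL8, the neutrophil chemoattractant, stood at 0.48 and MAP3K8 at -0.85.

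Targets of YAP and TAZ, the transcriptional co-activators that respond to cell stretch, were higher as a group. Of the 12 measured members (23 fixed), 11 were at least 1.5-fold higher, 9 at least 2-fold, and 0 lower. The median difference was 1.40, against 0.38 for random lists, and lay at the 100th percentile. Besides ANKRD1 and CCN2, the largest differences were those of FJX1 (2.66, from 5.21 to 7.87) and AJUBA (2.59, from 3.48 to 6.07), a LIM protein of adherens junctions whose static value lay within the background range. Without ANKRD1 and CCN2 the median was 1.33 over 10 genes, a removal chosen after the data were seen. The second, dimmer probe set of CCN2 had a difference of 0.96.

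Actin cytoskeleton and SRF target genes had a median difference of 0.68, at the 97.6th percentile, with 10 of 16 measured members (28 fixed) at least 1.5-fold higher and 0 lower. VCL, encoding the focal adhesion protein vinculin, was higher by 1.87 and ZYX (zyxin) by 1.31. PXN (paxillin) went from 5.17 to 6.67 and TPM1 (tropomyosin) from 5.37 to 6.85. Under a level filter at the upper quartile this list stood at the 96.7th percentile. Only 8 of 32 integrin, laminin and focal adhesion genes were measured by name. Their median was 0.25, at the 46.5th percentile, with CAVIN1, a coat protein of caveolae, higher by 2.65, THBS1 by 1.82 and BCAR1 by 0.71 (static value within the background range), while HMMR stood at -0.40. Of 7 measured stretch-sensitive channel genes (19 fixed), PANX1 was higher by 1.36 and PIEZO1 by 1.26. PKD1 stood at 0.28 and TMEM63B at 0.17, and the list lay at the 31.6th percentile.

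**Figure D2:**
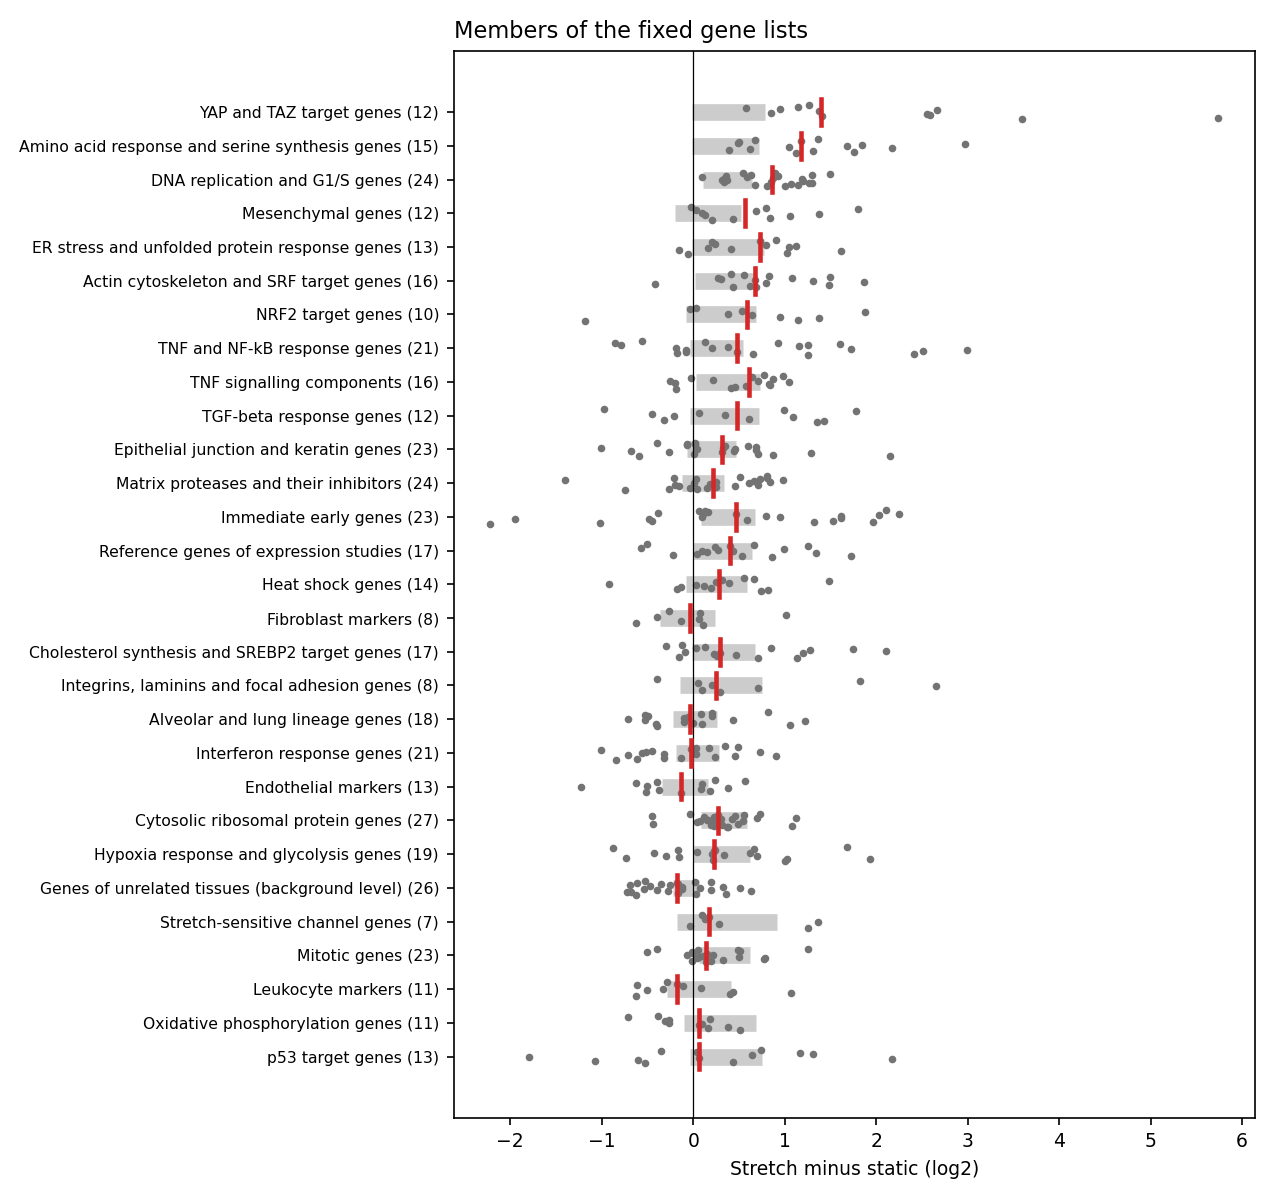
Log2 difference (stretch minus static) of each measured member of the fixed gene lists (grey points; number measured in parentheses), with the list median (red bar) and the middle 95% of medians of 10000 random lists matched on level (grey band). The medians of the YAP and TAZ targets (1.40), the amino acid response genes (1.18) and the DNA replication genes (0.86) lie to the right of their bands.

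Matrix proteases and their inhibitors did not stand apart. The median over 24 measured members (34 fixed) was 0.22, at the 85.9th percentile, with 8 at least 1.5-fold higher and 2 lower. TIMP3, a tissue inhibitor of metalloproteinases, stood at -1.40, within the background range on both arrays, and at -0.77 with its probe sets averaged, while TIMP2 was higher by 0.98, ADAM12 by 0.84 (static value within the background range) and BSG, an inducer of metalloproteinases, by 0.81. Mesenchymal genes had a median of 0.57, at the 98.5th percentile, with 6 of 12 measured members (23 fixed) at least 1.5-fold higher and 0 lower. LOXL2, a collagen cross-linking oxidase, was higher by 1.80, TWIST2 by 1.37, SNAI2 by 1.06 and SNAI1 by 0.84. The last 3, transcription factors of epithelial-mesenchymal transition, had static values within the background range, TWIST2 on both arrays, and the list lay at the 96.9th percentile after either quantile normalization or loess. Epithelial junction and keratin genes had a median of 0.31 (83.9th percentile), with 7 of 23 measured members (28 fixed) at least 1.5-fold higher and 3 lower. KRT7 was higher by 2.15, CLDN1 by 1.29 and KRT8 by 0.87, and the desmosomal cadherin DSC2 was lower (-1.01).

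Immediate early genes divided. FOS went from 7.33 to 5.11 (-2.22) and EGR1 from 8.69 to 6.74 (-1.95), and both had a second probe set of the same sign. With probe sets averaged, EGR1 stood at -1.33. In contrast, DUSP5, a nuclear ERK phosphatase, was higher by 2.25, MCL1, an anti-apoptotic BCL2 relative, by 2.11 and DUSP4 by 2.03. The dimmer probe set of DUSP5 had the opposite sign, and the mean of both was 0.95. Of 23 measured members (29 fixed), 11 were at least 1.5-fold higher and 3 lower, and the median of 0.47 lay at the 76.3rd percentile. The third lower member was FOSB (-1.02), while FOSL1 (1.96), MYC (1.61) and JUN (1.53) were higher. These 4 genes were chosen after their values were seen. TGF-β response genes had a median of 0.48 (80.0th percentile), with 6 of 12 members (25 fixed) at least 1.5-fold higher and 1 lower. The inhibitory genes SMURF1 (1.78), SMAD6 (1.43), SMAD7 (1.35) and TGIF1 (1.09) had the largest differences, with SMAD7 within the background range on both arrays and SMAD6 on the static array. With the level filter at the background bound, the TGF-β list kept 10 members and lay at the 23.3rd percentile.

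**Figure D3:**
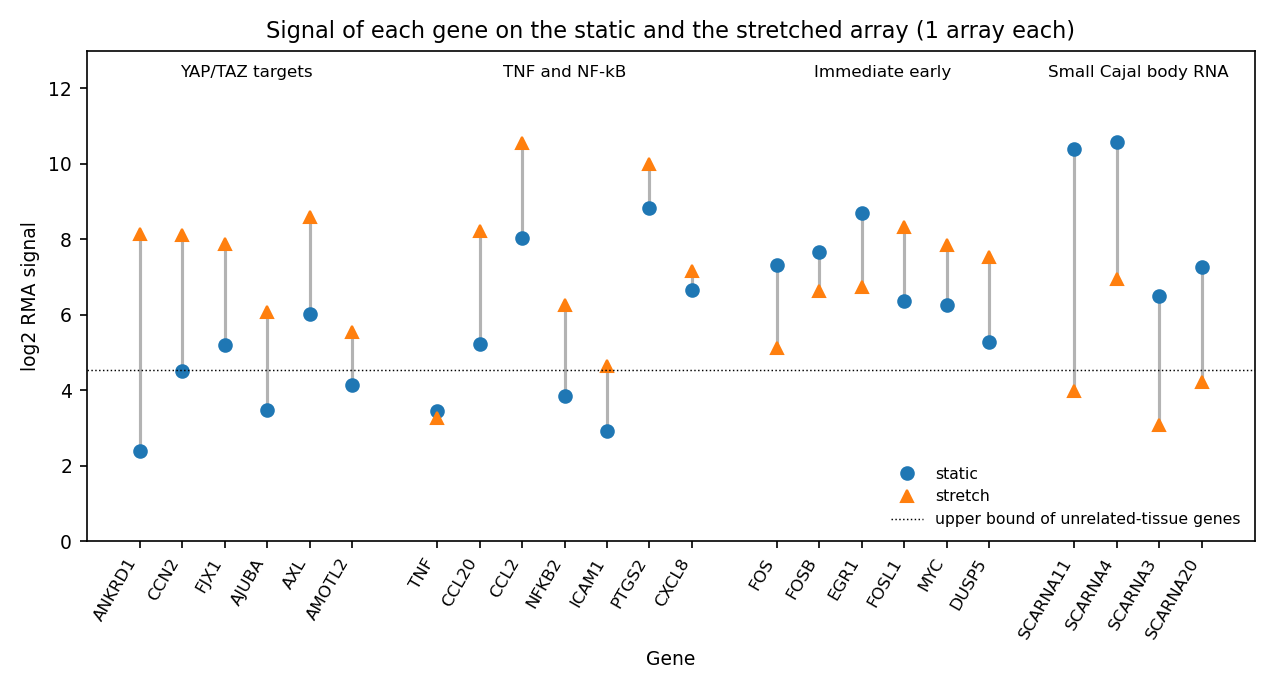
Log2 RMA signal of selected genes on the static (circles) and the stretched (triangles) array, with the upper bound of unrelated-tissue genes (4.55) dotted. AXL, AMOTL2, PTGS2, CXCL8, FOSB, FOSL1 and MYC were added after their values were seen. TNF lies below the line on both arrays, at 3.46 and 3.27.

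Genes of DNA replication and the G1/S transition were higher as a group, with 17 of 24 measured members (28 fixed) at least 1.5-fold higher and 0 lower. Their median difference of 0.86 lay at the 99.9th percentile. CLSPN, the checkpoint adaptor claspin, went from 3.71 to 5.21. MCM10 was higher by 1.30, UHRF1 by 1.30 and the helicase subunit MCM7 by 1.27. A second CLSPN probe set lay below the level filter, and the mean of both gave 0.64. Mitotic genes had a median of 0.14, at the 8.62nd percentile, with 3 of 23 (28 fixed) at least 1.5-fold higher and 0 lower. NDC80 (1.25), CDK1 (0.78) and CDC20 (0.77) were those, and BIRC5 stood at 0.51. The static values of CLSPN and NDC80 lay within the background range.

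Genes of the amino acid response and serine synthesis were also higher as a group. Of 15 measured members (25 fixed), 12 were at least 1.5-fold higher, 10 at least 2-fold, and 0 lower, and the median of 1.18 lay at the 100th percentile. STC2, a secreted glycoprotein, was higher by 2.97, the leucine sensor SESN2 by 2.17, VLDLR by 1.84 and PSAT1, of serine synthesis, by 1.76. Genes of ER stress shared some of these members and had a median of 0.73 (95.7th percentile), with 7 of 13 (25 fixed) at least 1.5-fold higher and 0 lower. ATF3 was higher by 1.61, ASNS (asparagine synthetase) by 1.12, TRIB3 by 1.05 and ATF4 by 1.03. After loess this list lay at the 98.0th percentile. Among p53 targets, SESN2 (2.17), AEN (1.31) and PLK3 (1.17, within the background range on both arrays) were higher and TP53INP1 was lower (-1.80). The p53 list had 5 of 13 members (23 fixed) at least 1.5-fold higher and 3 lower, with a median of 0.06 at the 8.22nd percentile, and lay at 2.26 after loess. The static values of SESN2 and ATF3 and the stretched value of TP53INP1 lay within the background range.

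Other stress and metabolic lists lay inside the middle 95% of matched random lists, except oxidative phosphorylation under stricter level filters. Heat shock genes had a median of 0.28 (60.3rd percentile), with 4 of 14 measured members (25 fixed) at least 1.5-fold higher and 1 lower. BAG3, a co-chaperone, went from 4.97 to 6.45, with HSPA1B at 0.82, HSPA1A at 0.74 and HSPA4L at -0.92. HSPA1A and HSPA1B are near-identical copies whose signals cannot be separated. NRF2 targets had a median of 0.59 (92.9th percentile), with 5 of 10 measured members (27 fixed) at least 1.5-fold higher and 1 lower. OSGIN1 stood at 1.88, SRXN1 at 1.37, TXNRD1 at 1.15 and HMOX1, heme oxygenase 1, at -1.18, with the static value of OSGIN1 within the background range. Hypoxia and glycolysis genes had a median of 0.23 (34.3rd percentile), with 7 of 19 measured members (32 fixed) at least 1.5-fold higher and 2 lower. ANGPTL4 stood at 1.93, DDIT4 at 1.68 and ADM at 1.02, and VEGFA went from 4.69 to 5.69. Cholesterol synthesis genes had a median of 0.29 (43.9th percentile), with 7 of 17 measured members (27 fixed) at least 1.5-fold higher and 0 lower. INSIG1 stood at 2.11, STARD4 at 1.75, SREBF2 at 1.28 and HSD17B7 at 1.20. The static value of STARD4 and both values of HSD17B7 lay within the background range. Interferon response genes had a median of -0.02 (30.3rd percentile), with 2 of 21 measured members (31 fixed) at least 1.5-fold higher and 4 lower. IFITM3 stood at -1.01, ISG20 at 0.91, IFIT1 at -0.84 and IFI35 at 0.73, with ISG20 and IFIT1 within the background range on both arrays and IFITM3 on the stretched array. Oxidative phosphorylation genes had a median of 0.06 (14.2nd percentile), with 0 of 11 measured members (32 fixed) at least 1.5-fold higher and 1 lower. Those measured were UQCR, CYC1 and COX genes only, and no fixed NDUF, SDH or ATP5 gene was measured by name. COX7A2 stood at -0.71, UQCRB at 0.51, COX7C at -0.39 and UQCRC2 at 0.38, with UQCRB in the background range on both arrays. The 9 and 8 measured oxidative phosphorylation genes past the level filter at the upper quartile and at the background bound lay at the 0.38th and 0.45th percentile. The median of ribosomal protein genes was 0.27 (32.1st percentile), with 4 of 27 measured members (44 fixed) at least 1.5-fold higher and 0 lower. RPS7 stood at 1.12, RPL9 at 1.08, RPS28 at 0.73 and RPS9 at 0.70, with RPS7 in the background range on both arrays. Reference genes of expression studies had a median of 0.40 (70.04th percentile), with 6 of 17 measured members (29 fixed) at least 1.5-fold higher and 0 lower. PPIA stood at 1.72, IPO8 at 1.34, VCP at 1.25 and SNRPD3 at 0.99, with the static value of IPO8 within the background range. None of the replication-dependent histone genes fixed in advance is named here (0 of 22).

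Markers of other cell types did not stand apart from random genes of their level. Fibroblast markers had a median of -0.04 over 8 measured members (55.7th percentile), with FBLN1 at 1.01, THY1 at -0.13 and MFAP4 at 0.06. Leukocyte markers had a median of -0.18 over 11 members (8.27th percentile), with CD68, a lysosomal protein, at 1.07, CD2 at -0.62, S100A9 at -0.61 and CSF1R at 0.44. Endothelial markers had a median of -0.13 over 13 members (34.1st percentile), with ERG at -1.23, FLT1 at -0.63, VWF at -0.52 and ENG at -0.40. Of these 11 genes, only CD68 and FBLN1 exceeded the background bound of 4.55 on either array. Alveolar and lung lineage genes had a median of -0.03 over 18 members (33.5th percentile). LPCAT1, an enzyme of surfactant lipid synthesis, stood at 1.22, SFTPA2 at 1.06, GATA6 at 0.82 and LAMP3 at -0.71, with SFTPA2 and LAMP3 in the background range on both arrays. The unrelated-tissue genes had a median of -0.18 (8.39th percentile), with GFAP at -0.72, PF4 at -0.69, MBP at 0.63 and LHB at 0.51.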

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

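A signal outside the named genes was present in probe sets to which the annotation used here gives no gene. Of 17854 such probe sets past the level filter, 2600 were at least 2-fold higher and 1493 at least 2-fold lower under stretch. This split was less uneven than that of the named genes (1349 higher and 275 lower). Probe set 16840590 went from 1.29 to 7.53, a difference of 6.24, and probe set 16900528 from 1.06 to 7.27 (6.21), both from static values within the background range. Probe set 16913572 went from 9.93 to 3.71 (-6.22) and probe set 17057462 from 9.88 to 4.28 (-5.60), with stretched values in that range. These probe sets are unnamed here, not without a gene, and no explanation was tested. With 1 array per condition, no test for outlying samples or for differences between subgroups could be made.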

How the results depend on the processing

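Removing the 2 members with the largest differences from the YAP and TAZ, amino acid response and DNA replication lists was chosen after the data were seen; every other alternative was planned. Genes at least 2-fold higher numbered 707 after quantile normalization, 794 after loess, 475 after centring on reference genes, 3042 at 1.5-fold and 357 at 3-fold. Genes lower numbered 443 after quantile normalization, 1198 after centring on reference genes, 977 at 1.5-fold, 48 at 3-fold, 158 with the level filter at the upper quartile and 138 with it at the background bound. The median of the TNF and NF-κB response genes was 0.65 with the median level filter, 1.05 and 1.16 with the upper-quartile and background filters (percentiles 99.98 and 100), and their mean was 0.71. The median was 0.22 after quantile normalization, 0.30 after loess and 0.0276 after centring on reference genes, with percentiles of 94.4, 97.0 and 94.6 inside the middle 95%.

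Other lists are given as the median minus that of random lists, and 181 of 213 such alternatives stayed within the SD of random lists. The centrings are left out of this count because they shift a list and its random lists alike. Loess and quantile normalization are in the count but shift a list and its level-matched random lists nearly alike. All 27 lists stayed within the SD after each of these 2, which says little on their stability. With the upper-quartile filter, matrix proteases stood at 0.35 and oxidative phosphorylation, over 9 members, at -0.57 (0.38th percentile). With the background filter, proteases stood at 0.35, TGF-β response at -0.14, interferon response at -0.23, oxidative phosphorylation at -0.56 and alveolar genes at 0.42. The median filter gave proteases 0.26 and endothelial markers -0.35. Averaging probe sets gave TNF signalling 0.0225. Means gave YAP and TAZ targets 1.66, integrins 0.38, cholesterol synthesis 0.23 and interferon response -0.20. Without matching on level, which adds the level trend, the values were 0.55 for TNF signalling, 0.41 for immediate early, 1.34 for YAP and TAZ, 0.62 for actin, 0.42 for TGF-β, 0.08 for mitotic, 0.80 for DNA replication, 0.01 for p53, 0.68 for ER stress, 1.13 for amino acid response, 0.22 for heat shock, 0.53 for NRF2, 0.17 for hypoxia, 0.23 for cholesterol, 0.01 for oxidative phosphorylation, 0.21 for ribosomal protein, 0.34 for reference and -0.18 for endothelial genes. The YAP and TAZ, amino acid response and DNA replication lists lay above the middle 95% of random lists under every alternative run. Of these, the centrings could not move them, loess and quantile normalization could move them little, and the median level filter kept all their members. The actin list did not lie above the middle 95% under the 2 stricter filters (96.7 and 96.0). Nor did the mesenchymal list under those (94.7 and 89.1) or after quantile normalization or loess. After loess the p53 list lay below it (2.26) and the ER stress list above it (98.0). Apart from TNF, averaging probe sets altered 10 of 137 named genes and moved 6 by more than the background SD. Those 6 were CCN2 (2.28), EGR1 (-1.33), TAB1 (0.26), DUSP5 (0.95), TIMP3 (-0.77) and CLSPN (0.64). The scalings shifted the 137 genes by at most 0.45, less than that SD of 0.48, so they say nothing on the stability of single genes. Stricter filters leave fewer members by construction, and otherwise the cause was not tested. No paired analysis was possible because each condition has 1 array, and for the same reason no replicate could be left out.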

Other observations

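Further gene groups were listed only after the highest genes had been seen and partly hold such genes, so their values describe the members and no percentile is given. Ribosome biogenesis genes had a median difference of 0.87 over 25 measured members, 16 of them at least 1.5-fold higher and 0 lower. Without RRN3, RRP12 and URB1, which prompted the list, the median over 22 members was 0.76. MYBBP1A was higher by 2.33 and NOP2 by 2.07, while NCL (nucleolin) stood at 0.23 and FBL (fibrillarin) at 0.37. Cytosolic aminoacyl-tRNA synthetase genes had a median of 0.81 over 17 members, 14 at least 1.5-fold higher and 0 lower, led by CARS1 (1.79) and GARS1 (1.51). Nucleotide synthesis genes had a median of 0.79 over 13 members, with CTPS1 (CTP synthase) at 2.71 and PFAS at 1.77.

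ERK pathway output genes had a median of 1.38 over 9 measured members, 5 of them at least 1.5-fold higher and 0 lower, with the receptor EPHA2 at 2.44, ETV4 at 1.82 and CCND1 at 1.38. SPRY2 stood at 0.01 and EPHA4, within the background range on both arrays, at -0.10. Of the EGF receptor ligands, EREG (2.90, from 6.77 to 9.67) and HBEGF (1.94, from a static value within the background range) were higher, and the remaining 3 measured ligands lay at background, with a median of 0.26 over all 5. The alternative NF-κB pathway, with MAP3K14 at 3.05 and NFKB2 at 2.41, had a median of 0.75 over 6 members. The loci that follow were chosen after their values were seen and were not tested as groups. On chromosome 8, MYC stood at 1.61, MIR1204 at 3.28, MIR1205 at 2.33 and MIR1206 at 2.51, while MIR1207 (0.85) and MIR1208 (0.27) lay within the background range on both arrays. On chromosome X, MIR221 stood at 4.18 and MIR222 at 1.23, the latter within that range on both arrays. The static values of MIR1204, MIR1205, MIR1206 and MIR221 lay within it too. These probe sets cannot tell a mature microRNA from its primary transcript. RRN3 was higher by 2.95 and its annotated pseudogene RRN3P2 lower by a difference of -1.98, with the static value of RRN3 and the stretched value of RRN3P2 within the background range.

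Of the tests that follow, those of the trend and of fibroblasts for YAP and TAZ targets were chosen after the result was seen. The excess of genes higher over genes lower (83.1% of those past 2-fold) was set against the level-dependent trend and the unlike value distributions of the arrays. The loess left 68.2% and quantile normalization 61.5%, between the bounds set in advance of 60 for a technical cause and 70 against one. Both corrections bring the bulk of the genes close to balance by construction, so the lower shares do not show scaling as the source. An excess made by scaling cannot be told apart from one made by stretch with 1 array per condition.

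The lower signals of small Cajal body RNAs were not removed by the level trend, since their level-adjusted median was -1.30 (bootstrap SE 0.27, over 23 RNAs). Each SE here resamples RNAs of the same 2 arrays and does not measure variation between cultures. A lower recovery of all short RNAs in the stretched sample could also produce these lower signals. The other short noncoding RNAs had a level-adjusted median of -0.18 (SE 0.06, over 442), short of the -0.5 set in advance for this cause. That bound was unfit because most of them lay near background. In addition, 429 of them were microRNA genes, whose probe sets cannot tell a mature microRNA from its primary transcript. The 106 above background, computed after the first value was seen, stood at -0.53 (SE 0.11). That value rests on microRNA gene probe sets, since the 13 other RNAs had a level-adjusted median of 0.09 (SE 0.25), with level-adjusted values of -1.63 for RPPH1, -0.41 for RMRP, -0.85 for VTRNA1-2, 0.09 for VTRNA1-3 and a median of 0.38 over 8 SNAR RNAs. These few RNAs went both ways, and TERC outside them stood at -1.15 on the same scale. No class of small nucleolar RNAs was among the named genes past the level filter, so these were not compared. Recovery cannot be told apart from an effect of stretch.

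The higher signals of YAP and TAZ targets exceeded those of random genes of the same level, which share the level trend. The level-adjusted median of 1.11 also lay at the 100th percentile. That percentile adds little, because the loess shifts a list and its level-matched random lists nearly alike. Fibroblasts in the stretched sample would raise their own abundant transcripts, but the median of the 8 measured fibroblast markers of 17 was -0.035, and DCN (1.40) and LUM (1.83) lay at background under stretch, while FBLN1 went from 4.23 to 5.24. A different cell density in the static and the stretched culture, which also alters YAP activity, may give the same pattern. With 1 array per condition, and neither the density nor the culture device in the labels, it cannot be told apart from stretch. A response of these targets to stretch stays a hypothesis, which static and stretched samples at a matched density would test.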
